A study of Mus musculus with 4 samples.

How the data were processed

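Total RNA from testes of hypogonadal mice was measured on 4 one-colour Affymetrix mouse oligonucleotide arrays, 1 array per sample. The deposited values are signal intensities on a linear scale, 1 per probe set and array, for 12488 probe sets. The array maker is read from the probe set names in the file, and the software that made the signals is not given in the sources used here. No detection calls were used here, so whether a probe set lay above background could not be judged from a call.

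The 4 arrays did not share a common level as deposited. Their medians were 37.5, 29.3, 25.4 and 48.3 for T+O replicate 1 and T+T replicates 1, 2 and 3, without the control probe sets. The means after removing 2% of probe sets at each end were 106, 84.1, 72.9 and 124. With the control probe sets included, that mean was 125 on T+T replicate 3 only, a round number that scaling software can produce. The table was therefore not treated as already scaled: each array was multiplied by a factor (0.915, 1.15, 1.33 and 0.779) that brought its trimmed mean to the mean of the 4. Only 1 value each on T+T replicates 1 and 2 was 0.

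The 66 control probe sets were left out before scaling, which left 12422. An offset of 10, the 25th percentile of all scaled values, was added before taking log2, so a fold change is on the log2(signal + 10) scale and understates the change of dim probe sets. Probe sets were kept where the mean over the 4 arrays was above the 40th percentile of all probe set means, a scaled signal of 22.7, which left 7453. Gene names came from the platform annotation supplied for the probe sets, updated by gene ID through a mouse RefSeq gene table of assembly GRCm38.p6, which held 10817 of the 10833 probe sets with a single gene symbol. A further 396 probe sets carried several symbols and 1193 are unnamed here. No gene was named from either kind. A gene was represented by its brightest kept probe set, which gave 5677 genes. Coordinates are not printed, because the file names no genome build.

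Groups were taken from the sample titles, which give 1 T+O array and 3 T+T arrays. The replicate numbers 1 and 2 of T+T come from the titles, and the number 3 was given in accession order to the T+T array whose title has no number. The descriptions do not settle the arm of every array. For T+O replicate 1 and T+T replicate 1, title and description match. The descriptions of T+T replicates 2 and 3 stop at the withdrawal and state no later testosterone. Grouping by title, and the alternative of reading these 2 arrays as withdrawn, were both fixed before the data were examined, as were the gene lists, the tests, the naming rule and all other settings except the block on the deposited level and the tests of the closing section.

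The difference T+T minus T+O was tested per probe set with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over the 7453 probe sets and a threshold of 0.05. All 4 arrays entered 1 fit with 2 residual degrees of freedom and 5.74 prior degrees of freedom. The lone T+O array is assumed to vary like the T+T arrays. Beside this test, probe sets were counted that lay at least 1.5-fold to the same side of the T+O array on all 3 T+T arrays. That count was also made for each other choice of 1 array against 3, and on 20 simulated data sets with no difference between the arms, since all 3 comparisons share the T+O array. Nothing in the labels says whether the arrays came from separate animals or pools, so the limma p-values per probe set measure only the spread between these samples. The number of arrays limits the precision.

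A set of 20 gene lists, holding 360 genes, was fixed from textbook knowledge. Of these genes, 293 had a named probe set and 225 passed the filter. Lists with at least 5 measured genes (18 of 20) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. At the preset correlation camera compares the genes of a list with all other genes, so its p-values do not measure the spread between arrays. Estimated correlations and limma's fry were alternatives. The rule for named genes took, in each direction, up to 12 genes past the threshold by size of change, filled up from the genes with the largest mean difference among those at least 1.5-fold apart on all 3 T+T arrays. It added up to 4 members of each list (the 2 highest and the 2 lowest), and a few fixed genes where measured, among them Rhox5, Star, Cyp17a1, Hsd3b6, Insl3 and Amh. Amh and Hsd3b6 fell below the filter, and 1 further fixed gene is not reported here. The rule left out both probe sets that passed the threshold, 1 because a brighter probe set stands for its gene and 1 because it is unnamed, and those 2 are named as exceptions.

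The procedure was tested on simulated data with the means and spreads of the 7453 probe sets and 200 of them changed between T+T and T+O. The test recovered 41 of 100 probe sets changed 2-fold and 88 of 100 changed 4-fold on the log2(signal + 10) scale, with 5 false calls. The noise was drawn independently from the spreads as moderated by eBayes, without array-wide effects, so the recovery may be overstated. In a simulation over the 5677 genes, drawn independently with a common spread, a shift of 1 on the log2 scale given to the Sertoli list was recovered (camera, adjusted p = 1.92e-14). In the data the estimated correlation between genes reached 0.56 in the endothelial list, so this overstates the power for lists of that kind. The alternatives were quantile and median scaling, offsets at the 10th and 50th percentile of the values (3 and 35), no filter or a filter at the 60th percentile, leaving out each T+T array, an eBayes fit without the trend, the mean of all probe sets of a gene, and the other reading of the labels.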

Results

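Hypogonadal (hpg) mice lack gonadotropin-releasing hormone and therefore make little testosterone, so that androgen can be given and withdrawn experimentally. Transcript levels in the testes of such mice were measured on 4 arrays. All animals had first been given testosterone propionate, an injectable ester of testosterone, for 2 weeks where the label states a duration, and it was then withdrawn. The group titled T+O holds 1 array, described as withdrawn. The group titled T+T holds 3 arrays, of which replicate 1 is described as given testosterone propionate again for 4 hours. The descriptions of T+T replicates 2 and 3 end with the withdrawal, so their arm rests on the title alone. The comparison implied by the titles is the response of the androgen-deprived testis to renewed testosterone. Across the 7453 probe sets kept, arrays correlated with Pearson's r between 0.943 (T+O replicate 1 with T+T replicate 1) and 0.968 (T+T replicates 1 and 2). T+T replicate 3 correlated with T+O replicate 1 at 0.956, with T+T replicate 1 at 0.953 and with T+T replicate 2 at 0.959. No array pair was near identical: at most 99 of 12422 deposited values were equal between 2 arrays.

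Past the adjusted threshold, 2 probe sets were higher in T+T than in T+O and none was lower. Over 20 simulations of arrays with no difference, a mean of 0.95 and at most 3 probe sets passed, so 2 is within the range without any change. A probe set of Slc2a3, which encodes the glucose transporter GLUT3, had a scaled signal of 142 on the T+O array and 645 ± 60.1 (SD, n = 3) in T+T. Its log2 difference was 2.10 with a standard error of 0.19 (limma, adjusted p = 0.026). A second and brighter Slc2a3 probe set was not higher: it had 1493 in T+O and 1183 ± 138 in T+T, a log2 difference of -0.34 (limma, adjusted p = 0.73). The direction for this gene is therefore uncertain. The other, 102796_at, has no gene name here and went from 45.3 to 417 ± 101, a log2 difference of 2.92 with a standard error of 0.28 (limma, adjusted p = 0.026). Both probe sets were named after their values were seen, because the naming rule represents a gene by its brightest probe set and takes no probe set without a gene name. Neither passed after quantile scaling, where the adjusted p was 0.052 for the Slc2a3 probe set and 0.066 for 102796_at in limma.

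Among probe sets that did not pass the test, the widest gaps had T+T below T+O, led by Sycp1, Nipbl and Smc4. On the same arrays the 3′ to 5′ signal ratio of the control gene Gapdh was 1.20 in T+O and 0.844 ± 0.039 in T+T. Sycp1, a component of the synaptonemal complex that pairs chromosomes in meiosis, had a signal of 389.9 in T+O against 13.5, 38.5 and 36.2 in the T+T arrays. Its log2 difference was -3.42 with a standard error of 0.42 (limma, adjusted p = 0.11). Smc4, a condensin subunit, had 1526 in T+O and 237 ± 78.8 in T+T, a log2 difference of -2.69 ± 0.34 (SE). Nipbl, which loads cohesin onto DNA, had 253 in T+O and 31.3 ± 12.6 in T+T. Smc2, the condensin partner of Smc4, had 68.3 against 11.2 ± 3.55. Zfp638, an RNA- and DNA-binding zinc finger protein, had 164 against 17.4 ± 5.99, and Zfp644 and Zfp62 had 424 against 92.7 ± 38.9 and 77.8 against 13.7 ± 4.18. Matr3, a nuclear matrix protein, had 1638 in T+O and 439 ± 98.8 in T+T on a probe set whose name marks cross-hybridisation within a gene family. Its other probe set went the same way, with a log2 difference of -1.27. The mRNA export adaptor Fyttd1 had 702 against 201 ± 56.2, and Rev3l, the catalytic subunit of DNA polymerase zeta, had 139 against 32.9 ± 12.1. Myo9a, an unconventional myosin, had 135 against 33.8 ± 9.16. Scx, a tendon transcription factor, had 200 against 52.2 ± 39.6, the loosest of this group.

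The genes on the other side were mostly dim in T+O. The brightest was Rnf10, a RING finger protein, with 475 in T+O and 1688 ± 401 in T+T, a log2 difference of 1.78 ± 0.27 (SE; limma, adjusted p = 0.13). Dnah8, a dynein heavy chain of the sperm flagellum, had 231 against 728 ± 245, but its second probe set differed by -0.53 on the log2 scale, so its direction is uncertain too. The fatty acid transporter Slc27a1 had 14.4 in T+O and 80.7 ± 15.6 in T+T. The motor protein Myo1c had 14.1 against 73.9 ± 16.99, and the polarity gene Llgl2 had 19.8 against 88.4 ± 6.66. Icmt, which methylates prenylated proteins, had 11.0 against 59.8 ± 2.40. The vesicle fusion ATPase Nsf had 19.8 against 80.3 ± 19.7, and the calcium sensor Ncs1 had 6.59 against 39.0 ± 11.9. The glutamate receptor subunit Grin2d had 8.51 against 51.2 ± 10.8, and the homeobox genes Pax4 and Msx3 had 17.4 against 72.4 ± 4.82 and 10.8 against 53.1 ± 15.6. H2-M10.1, a non-classical MHC gene, had 29.9 against 118 ± 19.2 on a probe set shared within its gene family. Its other probe set differed by only 0.21 on the log2 scale. For these dim genes the fold depends on the offset.

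**Figure D1:**
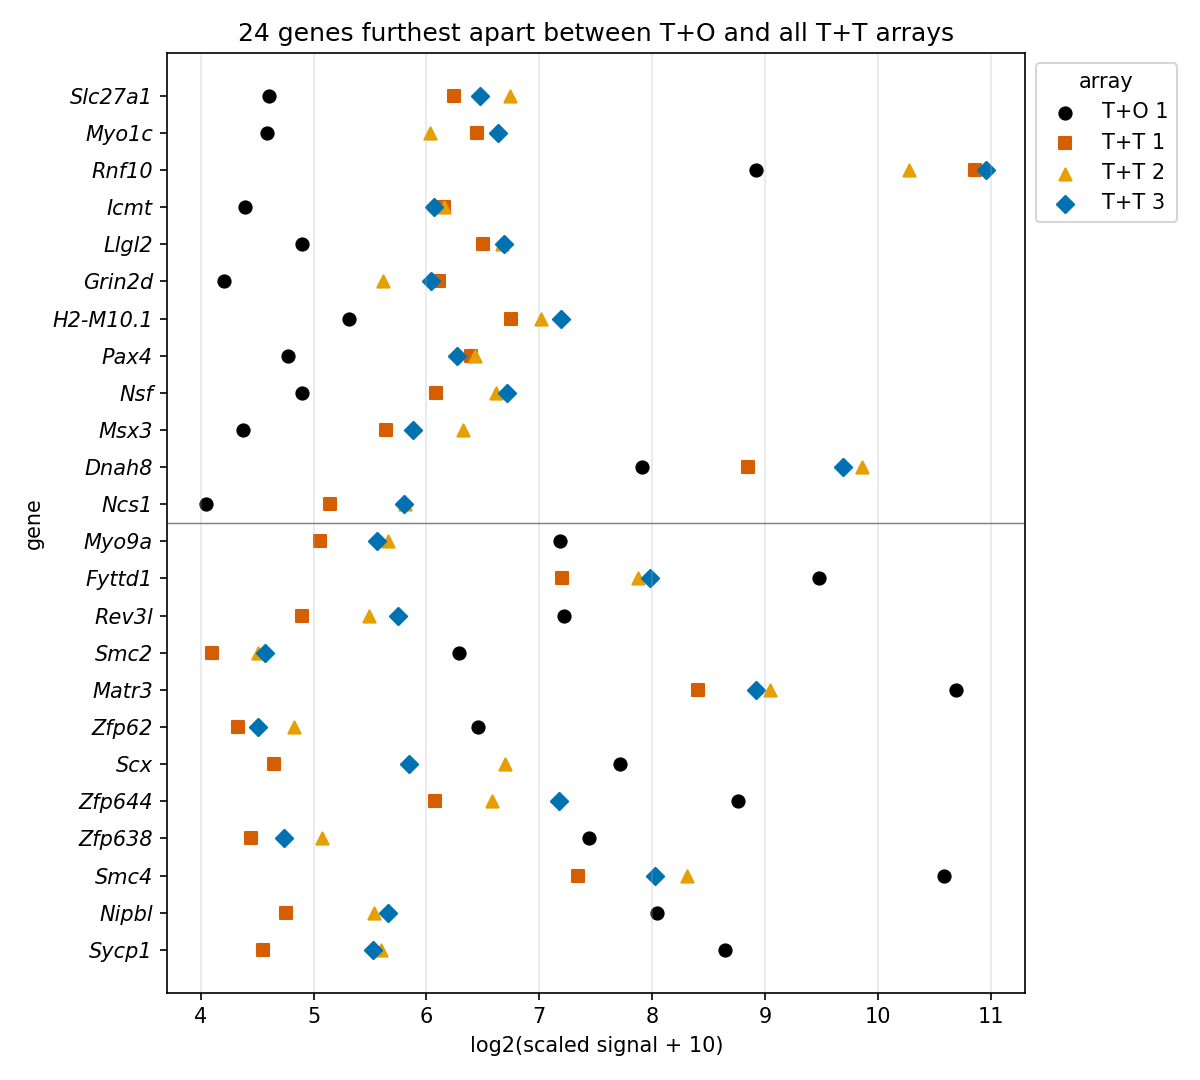
Scaled signal of 24 named genes on each array, on the log2(signal + 10) scale, with 1 point per array and no averaging. Genes above the grey line had all 3 T+T arrays at least 1.5-fold above the T+O array and those below it at least 1.5-fold below, with Sycp1 at 389.9 in T+O and 13.5 to 38.5 in T+T.

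In total, 136 probe sets were at least 1.5-fold higher and 165 at least 1.5-fold lower on all 3 T+T arrays than on the T+O array. Simulated arrays with no difference gave a mean of 54.45 higher and 55.05 lower, and at most 128 in all. Setting each T+T array against the other 3 gave 205, 149 and 194 such probe sets for replicates 1, 2 and 3, against 301 for T+O. Each T+T array thus also exceeded the simulated maximum. The simulation drew probe sets and arrays independently, without array-wide effects, so it sets too low a level for these arrays. At an unadjusted p under 0.05, limma gave 266 higher and 315 lower probe sets, where chance alone gives about 373 in all. The count past the adjusted threshold depends on the arrays: it was 63 without T+T replicate 1, 12 without replicate 2 and 1 without replicate 3, each from a fit with T+O as a lone array. Without T+T replicate 3, 653 probe sets were at least 1.5-fold apart. Of the 24 genes plotted, 20 passed without T+T replicate 1, 10 without replicate 2 and 0 without replicate 3.

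**Figure D2:**
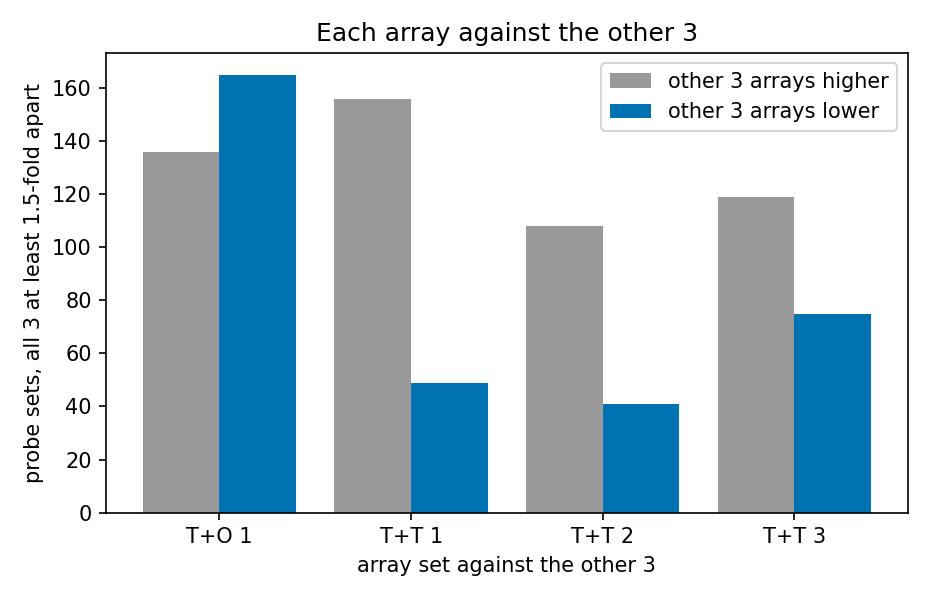
Number of probe sets (vertical axis) at least 1.5-fold higher or lower on the other 3 arrays than on the array named on the horizontal axis, both bars starting at 0. T+O gave 136 and 165, and T+T replicates 1, 2 and 3 gave totals of 205, 149 and 194.

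None of the 18 gene lists tested moved as a set (limma camera, lowest adjusted p = 0.69; adjusted p = 0.98 for every list with an estimated correlation). Before adjustment only the peritubular myoid list was below 0.05 in camera, at 0.047, and its adjusted p was 0.69 in limma camera.

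For androgen-responsive genes of the testis, none of 9 measured members passed over all probe sets or adjusted over the list alone. Rhox5, a homeobox gene of Sertoli cells known for its androgen response, had 106 in T+O and 130 ± 20.6 in T+T, a log2 difference of 0.26 with a standard error of 0.23. Drd4 had 96.8 against 135 ± 22.8 and Tsx 267 against 233 ± 21.9. Among 14 androgen-responsive genes of other tissues none passed by either adjustment. The clock gene Per1, which steroid hormones can induce, had 175 in T+O and 96.2 ± 10.4 in T+T, a log2 difference of -0.81 (limma, adjusted p = 0.35). Kap, a kidney androgen-regulated gene, had 22.8 against 32.5 ± 4.28.

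The somatic cells of the testis showed no list that passed. None of 12 Leydig cell genes passed by either adjustment. Star, which carries cholesterol into mitochondria, had 14.5 against 29.0 ± 14.8, and Cyp17a1, which makes androgen precursors, had 73.6 against 83.2 ± 18.5. The name of the Star probe set marks cross-hybridisation within a gene family, and its T+O signal lay under the filter level of 22.7. Its T+T signals were 22.5, 18.4 and 45.9 on replicates 1, 2 and 3. Hsd3b1 had 179 against 158 ± 23.8 and the Leydig hormone Insl3 34.3 against 35.4 ± 3.74. None of 17 Sertoli cell genes passed by either adjustment. Kitl, the ligand that supports spermatogonia, had 49.9 in T+O and 14.8 ± 2.41 in T+T, a log2 difference of -1.28 with a standard error of 0.39 (limma, adjusted p = 0.45). Gata4 had 87.9 against 146 ± 48.4. Of 10 peritubular myoid and smooth muscle genes 7 lay above T+O and none passed by either adjustment, with Des at 29.3 against 50.2 ± 10.4 and Cnn1 at 21.0 against 38.4 ± 9.65. None of 5 endothelial genes passed by either adjustment, with Eng at 108 against 148 ± 12.8 and Cd34 at 25.8 against 42.6 ± 3.77. None of 12 macrophage and immune genes passed by either adjustment, with C1qa at 63.1 against 94.4 ± 14.0 and Laptm5 at 37.3 against 66.1 ± 16.5. The Laptm5 probe set carries the same mark of cross-hybridisation as that of Star. Among 6 red blood cell genes, none of which passed by either adjustment, Hba-a1 had 327 against 327 ± 27.1 and Bpgm 132 against 167 ± 22.1.

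Germ cell lists did not pass either. None of 8 spermatogonia genes passed by either adjustment. Dazl, an RNA-binding protein needed by germ cells, had 166 in T+O and 82.0 ± 20.02 in T+T, a log2 difference of -0.96 (limma, adjusted p = 0.41). Stra8, which starts meiosis, had 77.2 against 49.96 ± 11.5, and Uchl1 288 against 352 ± 10.4. Of 8 meiotic genes, Sycp1 alone passed adjusted over the list alone (limma, adjusted p = 0.00038), and none passed over all probe sets. The other 7 lay between -0.08 and 0.57 on the log2 scale, the highest being the meiotic cyclin Ccna1 at 256 against 388 ± 62.2. None of 19 spermatid genes passed by either adjustment. Tnp2, a transition protein of condensing spermatids, had 7942 against 9931 ± 1279, a difference whose sign turned after quantile scaling. The chaperone Clgn had 1305 against 894 ± 205 and the acrosomal gene Acrv1 266 against 207 ± 40.4.

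Of 21 cell cycle genes, Bub1 and Top2a passed adjusted over the list alone and none passed over all probe sets. Bub1, a mitotic checkpoint kinase, had 206 in T+O and 82.7 ± 19.0 in T+T, a log2 difference of -1.24 with a standard error of 0.28 (limma, adjusted p = 0.26 over all probe sets). Top2a, the replicative topoisomerase, had 202 against 89.9 ± 16.8. Cdc20, which drives exit from mitosis, lay the other way at 1107 against 1480 ± 197. None of 18 heat shock and chaperone genes passed by either adjustment, with Hsp90aa1 at 4065 against 2339 ± 861, Hsp90b1 at 1467 against 837 ± 306 and Dnajb1 at 489 against 632 ± 122. No member passed by either adjustment in the remaining lists. Immediate-early genes (16 measured) had Mcl1 at 106 against 74.6 ± 15.3 and Fosb at 57.6 against 85.5 ± 36.8. Cholesterol synthesis genes (9 measured) had Idi1 at 182 against 102 ± 38.8 and Fdps at 551 against 693 ± 81.2. Extracellular matrix genes (19 measured) had Timp2 at 40.2 against 73.8 ± 9.60 and Timp3 at 123 against 83.3 ± 9.16. Cell junction genes (13 measured) had Cdh2 at 88.3 against 53.3 ± 10.6, Tjp1 at 116 against 73.0 ± 22.3 and Cdh1 at 116 against 168 ± 25.7. Retinoid genes (7 measured) had Aldh1a2 at 113 against 149 ± 26.0 and Rxrb at 417 against 348 ± 44.1. Too few genes were measured to test the epididymis list, with Gpx5 at 39.3 against 38.6 ± 12.9, and the adipose list of 4 genes, with Lipe at 260 against 186 ± 44.0. The median and the mean of the log2 differences had opposite signs for both androgen lists and for the Sertoli, meiotic, spermatid and cell cycle lists. For cholesterol synthesis both were below 0 while camera ranked the list upward.

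**Figure D3:**
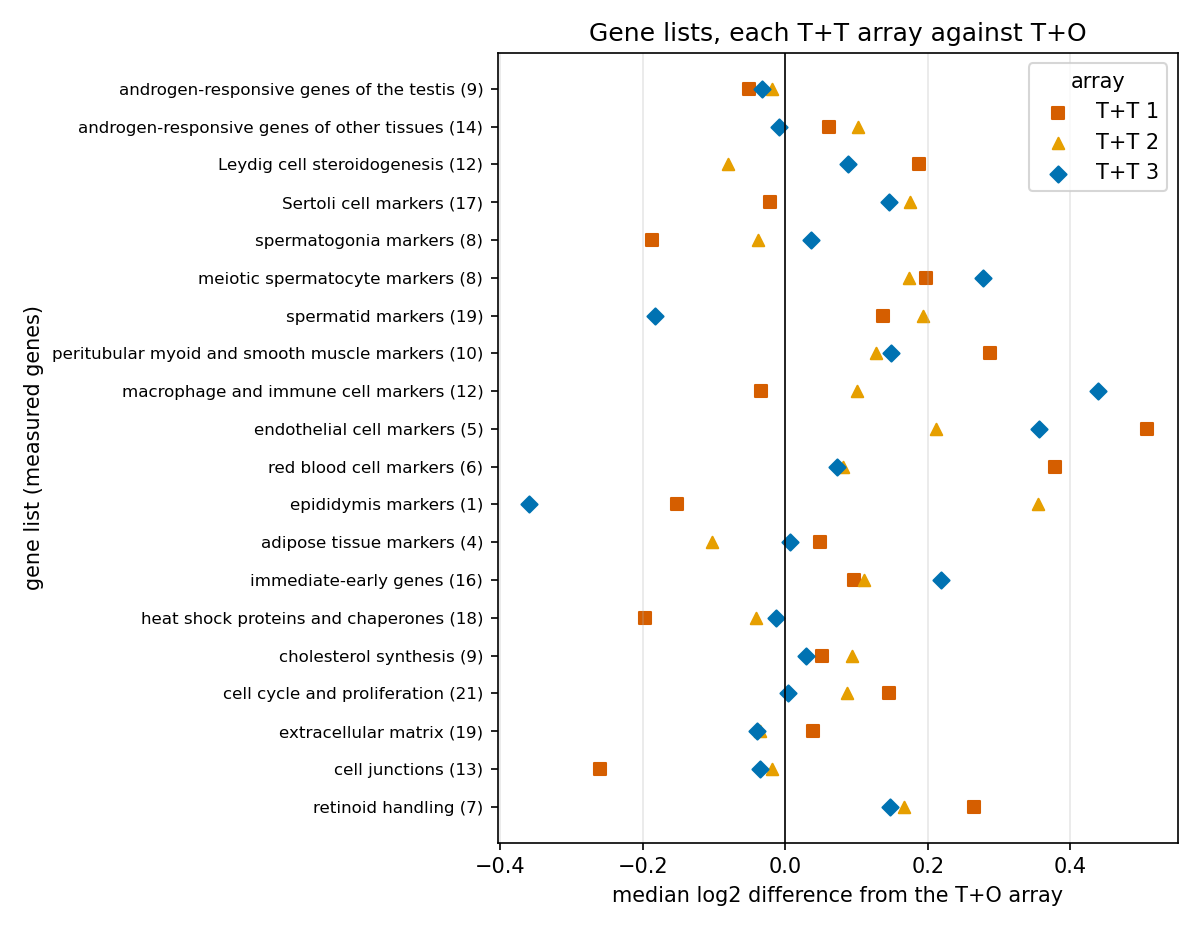
Median log2 difference from the T+O array (horizontal axis) of the measured genes in each list, with 1 point per T+T array and the number of measured genes in brackets. Most lists lie within 0.3 of 0, and the T+T arrays fall on both sides of 0 for the spermatid list (0.14, 0.19 and -0.18) and the Leydig list (0.19, -0.08 and 0.09).

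T+O replicate 1 and T+T replicate 1 are the arrays whose title and description match, and they hold the 4 hours of renewed testosterone without dispute. The label of T+T replicate 1 gives no duration for the first treatment, where that of T+O replicate 1 gives 2 weeks. Between them 509 probe sets were at least 1.5-fold higher and 820 at least 1.5-fold lower in T+T replicate 1. This is 1 array against 1 array and has no replicate check. The lowest were Sycp1 at -4.09 on the log2 scale, Nipbl at -3.28, Smc4 at -3.25, Scx at -3.07 and Zfp638 at -2.99. On the other side 102796_at was at 3.0, the autophagy gene Uvrag at 2.33 and the protease inhibitor Serpina3n at 2.30, the last 2 named only after this pair was seen. The Slc2a3 probe set that passed the test was at 1.97, Rnf10 at 1.94, Grin2d at 1.899 and Myo1c at 1.85. Rhox5 differed by 0.10, Per1 by -0.67, Star by 0.41 and Kitl by -1.30. List medians for this pair ranged from -0.26 for cell junctions to 0.51 for endothelial markers.

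When T+T replicates 2 and 3 are read as withdrawn, the comparison becomes T+T replicate 1 against the other 3 arrays. No probe set passed in limma, 380 had an unadjusted p under 0.05, and 49 were at least 1.5-fold higher and 156 at least 1.5-fold lower in T+T replicate 1 than on all 3 others. Under this reading Sycp1 differed by -2.04 with a standard error of 1.06, since T+T replicates 2 and 3 lie near replicate 1 for this gene. Rhox5 was at -0.14 and Star at -0.06, with signs opposite to the grouping by title. The lowest adjusted p of any gene list was 0.11 in camera.

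The mouse control genes that are probed at both ends of the transcript set the T+O array apart in part. The ratio of 3′ to 5′ signal for Gapdh was 1.20 on the T+O array and 0.844 ± 0.039 (SD, n = 3) on the T+T arrays. For pyruvate carboxylase it was 3.76 against 1.896 ± 0.12. For Actb it was 1.53, within the T+T values of 1.66, 1.40 and 1.17. The Gapdh and pyruvate carboxylase ratios set T+O apart from all 3 T+T arrays, as Sycp1, Smc4 and Nipbl do, and the Actb ratio does not.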

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

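The block on the deposited level and the narrower condensin and cohesin family were chosen after the data were examined, and every other setting before. That family's median became -0.27 from -0.32. No paired analysis was possible because the T+O group has a single array and its number pairs it with nothing. Of the count of 2 probe sets past the adjusted threshold, 0 remained after quantile scaling, with no filter (more probe sets tested), without the intensity trend, with T+T replicates 2 and 3 read as withdrawn and with the block on the deposited level. There were 6 after median scaling and 6 with the offset at the 50th percentile, where Sycp1, Nipbl, Smc4 and Zfp638 passed as lower in T+T. Leaving out 1 T+T array gave 1 to 63. Of the 301 probe sets at least 1.5-fold apart, 136 were higher and 165 lower. These became 155 (57 higher, 98 lower) with the offset at the 50th percentile, 523 (215 and 308) with no filter, and 167 (62 and 105) with the filter at the 60th percentile. Leaving out 1 T+T array gave 416 to 653, with 218 to 232 higher and 198 to 421 lower, since fewer arrays have to lie on 1 side. Reading T+T replicates 2 and 3 as withdrawn gave 49 higher. For the 1 pair of arrays whose labels match, the 1329 probe sets at least 1.5-fold apart became 733 with the offset at the 50th percentile and 2345 with no filter. The number of gene lists that passed was 0 under every setting run, with the lowest adjusted p between 0.11 and 0.98.

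Of the named genes, Tnp2 became -0.021 and Hba-a1 0.0204 on the log2 scale after quantile scaling, and Hsd3b1 became 0.047 and Hba-a1 0.10 with the block. With the block, the difference is that of T+T replicate 3 alone from T+O. Leaving out 1 T+T array gave -0.0556 to 0.0601 for Hba-a1, -0.00467 to 0.101 for Insl3 and -0.256 to 0.101 for Gpx5. It gave 0.15 to 0.35 for Rhox5, which was 0.49 with the block. Reading T+T replicates 2 and 3 as withdrawn turned Dnah8 to -0.31, Ncs1 to -0.0785, Rhox5 to -0.14, Star to -0.0596, Gata4 to -0.0399, Des to -0.17, C1qa to -0.10, Lipe to 0.25, Fosb to -0.34 and Timp2 to -0.0031. None of these passed the test in the settings where it turned. No detection calls were used, so what signal over background limits could not be set.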

Other observations

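The tests of array splits, control genes, gene length, gene density, meiotic cells and array labels were chosen after the results were seen. The 2 gene family tests were set before their values were known, after the genes that prompted them had been seen, and the narrower family below was added after.

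Other genes of the machinery that holds and folds chromosomes lay below T+O together with Smc2, Smc4 and Nipbl, on arrays where the 3′ to 5′ ratio was 1.20 in T+O against 0.844 ± 0.039 in T+T for Gapdh and 3.76 against 1.896 ± 0.12 for pyruvate carboxylase. Leaving those 3 out, 9 genes of a list of condensin, cohesin and related genes were measured, and 8 lay lower in T+T, with a median log2 difference of -0.32 (limma camera, adjusted p = 0.0027 over the 2 families tested). With an estimated correlation between genes in place of the fixed one, the camera p was 0.079. The estimated correlation was -0.11, below the fixed 0.01, so correlated genes do not account for that higher p. With an estimated correlation camera uses the 2 residual degrees of freedom of the arrays, and with the fixed one it counts genes. Smc6 belongs to a related complex and is neither condensin nor cohesin. Without it and its relatives 7 of 8 genes lay lower, with a median of -0.27, and the camera p was 0.0059, or 0.10 with an estimated correlation. Smc3, a core cohesin subunit, differed by -1.71, Smc6 by -0.94, Stag2 by -0.91 and Stag1 by -0.55, and Stag3, the meiotic cohesin subunit, by -0.32. Rad21, also a core cohesin subunit, differed by -0.18 only. The condensin subunits Ncaph and Ncaph2 differed by -0.22 and -0.049, and Mau2, the partner of Nipbl, lay higher at 0.18. The larger differences were thus in Smc3, Smc6, Stag2 and Stag1, and not in these condensin and loader genes. The median stayed between -0.31 and -0.37 under the other scalings and without each T+T array. With T+T replicates 2 and 3 read as withdrawn the median was -0.27 and the camera p 0.34. After the trends with gene length and gene density were removed, the median was -0.29 and the camera p 0.0042. A lower level of this family in T+T is a hypothesis that these arrays leave open, since all of it rests on the single T+O array. The 46 other Zfp-named zinc finger genes did not move together (limma camera, adjusted p = 0.55), so the low values of Zfp638, Zfp644 and Zfp62 do not extend to that family.

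The T+O array stood apart from the other 3 at 301 probe sets, more than the highest other array at 205. The 4 ways to set 1 array against 3 are too few for a share under 0.05: only 1 of them, the real one, gave as many, and likewise 1 for the 2 probe sets past the threshold, where the highest other gave 0. Over 20 simulations with no difference, a mean of 0.95 and at most 3 probe sets passed, so those 2 calls could be chance. Log2 differences went with the length of the gene on the genome (Spearman's rho = -0.20 over 5671 genes, which are not independent) and with gene density (0.15). Set against the other 3 in the same way, T+T replicate 1 gave 0.22 for length and -0.24 for density. T+T replicate 2 gave 0.11 and -0.095, and T+T replicate 3 gave -0.095 and 0.17. Trends of this size are therefore not particular to the T+O array. The signs were the same for T+O and T+T replicate 3 and opposite for T+T replicates 1 and 2. The same pairing returns in the splits of 2 against 2 below. The 133 genes lower on all 3 T+T arrays had a median length of 37802 bp, against 18942 bp over all genes. Within 500 kb they had a median of 10 protein-coding genes, against 17 over all genes. The 84 higher genes, at 19837.5 bp and 17, lay near the medians of all genes. After the fitted length and density trends were removed, 192 of 217 genes remained at least 1.5-fold apart, so the fitted trends account for few of these gaps. Trends this weak could hardly have removed more, so length or density as a cause is not decided. Transcript length and probe position were not tested. Unequal RNA integrity or labelling may contribute: 2 of 3 control genes had a 3′ to 5′ ratio on the T+O array outside the T+T values, and the third did not, so this stays open beside the testosterone given again. Fewer meiotic cells of every stage in the T+T samples would lower all their transcripts. The median of the 7 other meiotic markers was 0.13 while Sycp1 was at -3.42, which argues against such a general loss as the cause for Sycp1. The markers were not split by stage, so a loss limited to some stages was not tested.

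Setting T+O and T+T replicate 3 against T+T replicates 1 and 2 gave 941 probe sets at an unadjusted p under 0.05, more than the 178 and 163 of the other splits of 2 against 2, although none passed adjustment. T+T replicate 3 has no number in its title and its description names no renewed testosterone, so a wrong arm label might account for this. Its correlation with T+O minus its higher correlation with a T+T array was -0.0025, too small either way to decide. The same 2 arrays had the higher deposited level, and after scaling 3 of 4 bacterial hybridisation controls were still higher on both, so a shared processing batch cannot be told apart from a label error here. With that level as a block, no probe set passed in limma and 642 had an unadjusted p under 0.05, from 1 residual degree of freedom. T+T replicates 1 and 2 share a block level, so the difference in this fit is T+T replicate 3 minus T+O, 1 array against 1. By that difference 102796_at was at 2.53 instead of 2.92 on the log2 scale, the Slc2a3 probe set at 2.11 instead of 2.10 and Sycp1 at -3.12 instead of -3.42. These were already known to lie at least 1.5-fold from T+O on T+T replicate 3, so their gaps cannot test for a batch. For several smaller differences, T+T replicate 3 alone lay further from the mean of the T+T arrays for their size. Star was at 1.19 instead of 0.60, Rhox5 at 0.49 instead of 0.26, Tnp2 at 0.090 instead of 0.31 and Gpx5 at -0.36 instead of -0.052. Hsd3b1 and Hba-a1 had the opposite sign.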
